A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

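The series holds 15 libraries in 12 groups, each a pool of budding yeast cells with a plasmid library of N-terminal variants of Phm8 or Gpm3 fused to a tandem fluorescent timer. Wild type, gid9 deletion and gid11 deletion cultures were kept at 30 °C in glucose medium (synthetic complete, no histidine) until log phase and then moved to ethanol medium for 24 h, per the labels' protocols. Cells were then sorted into 8 bins by the timer's readout and each bin was grown to saturation, per the labels' protocols. Plasmids were isolated, the variable region was amplified with a barcode for each bin, the products were pooled in proportion to the cells sorted, and a second PCR added sample barcodes, per the labels' protocols. The submitters' processing notes name FastQC 0.11.9, cutadapt 4.0 and UMI-tools 1.1.2 with no role for any of them. Whether reads were collapsed by molecular identifiers is not given in the sources used here.

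The values deposited are counts of reads per DNA sequence of the variable region and bin barcode, with no normalization, per the file headers and the values themselves. Which barcode marks which bin is not given in the sources used here, so the order was inferred from the reads, without use of the genotypes. Barcodes that share variants more often were placed next to each other, over all 20160 orders (an order and its mirror being 1) and 15 libraries. The same order was best by 2 criteria, with a score of 5.47 against 5.02 for the next, which exchanges bins 7 and 8. When each library was taken alone it ranked 1 or 2 in 12 of 15 and 6 at worst by the sharing of adjacent barcodes, but by the distance between barcodes it ranked 1 to 20 in 7 libraries and 182 to 1345 in the other 8, among them all 6 of MXZ-Phm8. The end called bin 8 was set so that the native variants lie in higher bins in the deletions, which held in 10 of 10 comparisons within a batch. The word "higher" therefore means nearer to the end at which native variants lie in the deletions. As a hint on this end from other data, wild type PSI in MX9-Phm8 and the number of hydrophobic residues had a Spearman rho of −0.277 over 5327 peptides.

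The native residues 2 to 10 were taken as the most frequent sequence, the same in the 3 MX9 libraries of each protein. No genome was given, so no coordinates are used, and the table of gene names of assembly R64 served only for the names of 4 genes, of which 4 matched. DNA sequences were translated, those with the same residues were summed, and those with a stop codon were kept apart. The PSI of a variant is the sum over bins of bin number times reads, divided by its reads. Variants needed 100 reads in every library compared. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and biopython 1.88, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16.

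For MXZ-Phm8, limma (lmFit and eBayes) was fitted to the PSI of the 6 libraries, 2 per genotype, for 400 variants and, separately, for 40 residue means, each the mean over the 20 residues at the other position. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. The 17 residue lists were tested with camera at its preset correlation of 0.01, adjusted over the lists. They group position 2 as Thr, Ser, Pro, other small residues (Ala, Cys, Gly, Val), the NatB class (Asp, Glu, Asn, Gln), bulky hydrophobic (Phe, Ile, Leu, Met, Trp, Tyr) and basic (His, Lys, Arg). They group position 3 as aliphatic (Ile, Leu, Met, Val), aromatic (Phe, Trp, Tyr), acidic (Asp, Glu), basic (His, Lys, Arg), polar (Cys, Asn, Gln, Ser, Thr), Pro, and Gly or Ala. The last 3 lists hold Thr2 with an aliphatic or aromatic, a charged or polar, or an Ala, Gly or Pro residue 3. Library types with 1 library per genotype were described without a test: PSI with its counting error, and for each list the percentile of its median difference among 10000 random lists of the same size matched on reads in 10 bins of reads. MX9 single substitutions were listed by position, and over positions 4 to 10 by Pro, Asp or Glu, basic and hydrophobic residues. In MX9-Phm8, where over 50% of reads carried more than 1 change, each residue was averaged over all peptides that carry it, as the plan required. The comparisons, tests, thresholds, lists and 12 of the alternatives for each MXZ-Phm8 count were chosen before the data were examined.

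The labels give each library a sort batch, and the replicate number of MXZ-Phm8 marks a shared batch, so the libraries are paired by design. Deviations from the group means correlated over 400 variants with r = −0.0314 between wild type and gid9 deletion, −0.0191 between wild type and gid11 deletion and 0.206 between the deletions. A correlation over variants leaves out shifts of whole libraries, so it cannot show whether the batches share a shift. Median PSI was higher in batch 1 than in batch 2 in wild type (6.78 and 6.38), gid9 deletion (5.99 and 5.36) and gid11 deletion (6.47 and 5.40). The planned fit has no block, and the fit with the batch as a block was an alternative. The labels do not state that replicates come from separate cultures, so p-values measure only the spread between samples. In the planned fit limma gave every variant the same standard error, and likewise every residue mean, so this spread was pooled over variants. Variants of a library share its shift, so these p-values count as independent values that are not. Counting errors and intervals cover the sampling of reads only. Whether reads were collapsed by molecular identifiers is not known, and PCR reads that were not collapsed are not independent molecules.

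The named variants follow a rule fixed with the plan. It takes the native variant of each library, and in each MXZ-Phm8 comparison the 10 largest rises and falls past the threshold that had the same sign in both batches, of which there were 0. It also takes the 5 residues per position with the largest absolute difference of the residue mean, and in each comparison of single libraries the 10 highest and lowest differences among variants with 500 reads in both. Every position mean of MX9 and, as examples of a list, its 3 largest absolute differences complete it. Anything else named is said to be chosen after its values were seen, as were the variants named under alternative settings.

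Alternatives changed the read minimum (1, 30 or 500), the weight of bins, centring on the library median, a floor of 5% per bin, the median bin, the mean over synonymous sequences (30 reads each), the variance trend, the block, the libraries in the fit, the test (edgeR on reads in bins 5 to 8 against 1 to 4) and the correlation in camera, and left out each library in turn. Added after the data were seen were the subtraction of the stop profile scaled to bin 2, leaving out reads in bins 1 to 3, each with and without centring, the exchange of bins 7 and 8, and centring with the block and with each library left out. No library was left out of the planned comparisons.

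The scripts were tested on simulated data. With a spread between libraries as in the data and no shift of whole libraries, limma called 54.5%, 80.3% and 92.6% of variants changed by 0.5, 1 and 2, and 3.5% of unchanged ones. With shifts of whole libraries it called 0%, 1.52% and 63.2%, and after centring 51.5%, 86.4% and 97.1%. Only 200 of the 400 simulated variants were unchanged, and the rest moved in both directions. The adjustment of p-values is more lenient where so many variants change. These shares are therefore not the power in the data, where centring called 1 variant in the gid9 deletion and 4 in the gid11 deletion. Simulated bin orders were recovered in 10 of 10 cases, and 2 of 100 unchanged lists exceeded the 95th percentile. The simulated variants peaked inside the range of bins, whereas most MXZ-Gpm3 reads lie in bin 8. Recovery of the simulated orders therefore does not settle the order of bins 7 and 8. The standard error of each MXZ-Phm8 difference was 0.592 for a variant and 0.526 for a residue mean, and total reads per library lay between 5499518 and 80558785.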

Results

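The data describe how the N-terminus of a yeast protein sets its stability, and how that depends on the GID complex, a ubiquitin ligase of budding yeast that marks metabolic enzymes for degradation. In each of 15 libraries, yeast cells carried a reporter in which Phm8 (PHM8, YER037W) or Gpm3 (GPM3, YOL056W, a homolog of phosphoglycerate mutase) was fused to a tandem fluorescent timer, a pair of fluorescent proteins whose colour ratio reports how long the fusion survives. Cells were sorted into 8 bins by that ratio, and the reads of each N-terminal variant were counted in every bin. The protein stability index (PSI) used below is the mean bin of a variant's reads, on a scale from 1 to 8. In the MXZ libraries the residues 2 and 3 after the start methionine were varied, giving 400 amino acid pairs. In the MX9 libraries the residues 2 to 10 were varied. Each library was measured in wild type cells, in a gid9 deletion (Gid9 is encoded by FYV10, YIL097W, and belongs to the catalytic module of the ligase) and in a gid11 deletion (GID11, YLR149C, encodes a substrate receptor of the ligase), after 24 h in ethanol medium. MXZ-Phm8 had 2 libraries per genotype, sorted in separate batches, and MXZ-Gpm3, MX9-Phm8 and MX9-Gpm3 had 1 library per genotype. Total reads per library lay between 5499518 (MX9-Gpm3, gid11 deletion) and 80558785 (MX9-Phm8, wild type), and the MXZ-Phm8 libraries had between 17612178 and 22301991. All 400 residue pairs had at least 100 reads in each MXZ library.

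The variant with the protein's own residues was read first in every library, because the deleted genes themselves are not measured here. It is only a limited check on the genotype labels, since the upper end of the scale was set from these variants. An exchange of wild type and deletion labels throughout would pass it, and it does not tell the deletions apart. The native Phm8 peptide, TIAKDYRTI at residues 2 to 10, had a PSI of 4.69 in wild type, 6.95 in the gid9 deletion and 6.85 in the gid11 deletion in the MX9-Phm8 libraries, from 4014047, 3384859 and 3623011 reads. The native Gpm3 peptide, TVTDTFKLF, had a PSI of 4.20 in wild type, 7.53 in the gid9 deletion and 7.89 in the gid11 deletion in MX9-Gpm3. In MXZ-Gpm3 the native pair Thr2-Val3 had a PSI of 4.42, 7.95 and 7.62 in the same order. In MXZ-Phm8 the native pair Thr2-Ile3 had a PSI of 3.76 ± 0.277 (SD, n = 2) in wild type, 4.91 ± 0.624 in the gid9 deletion and 5.50 ± 0.631 in the gid11 deletion. The difference from wild type was 1.15 in the gid9 deletion (SE 0.592; limma, adjusted p = 0.262), with 1.78 in batch 1 and 0.511 in batch 2. It was 1.74 in the gid11 deletion (adjusted p = 0.446), with 2.38 in batch 1 and 1.099 in batch 2. With the sort batch as a block the same differences had adjusted p = 0.0140 and 0.000342, and over all alternatives tried adjusted p ran from 6.16e-08 to 0.722 for the gid9 deletion and from 3.63e-07 to 0.884 for the gid11 deletion. The order of the bins was inferred from the reads, and its upper end was set so that native variants lie higher in the deletions in all 10 comparisons within a batch, so the direction of these native changes is not independent evidence.

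**Figure D1:**
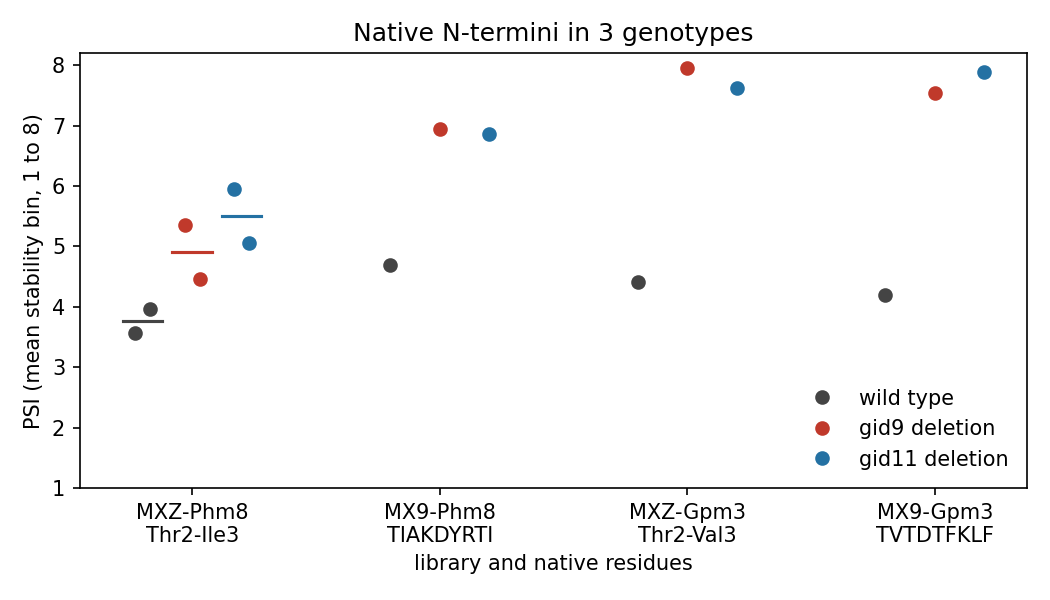
PSI (mean bin, 1 to 8) of the native N-terminus in wild type, gid9 deletion and gid11 deletion cells, for each of the 4 library types; points are libraries and, for MXZ-Phm8, lines mark the mean of the 2 batches. In MX9-Phm8 the native peptide lies at 4.69 in wild type and at 6.95 and 6.85 in the deletions.

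The comparison of the gid9 deletion with wild type in MXZ-Phm8 asks which residues 2 and 3 make Phm8 depend on the ligase's catalytic module. Variants that began with Thr2 had a median PSI of 4.49 in wild type, against 6.63 for Ser2 and 6.59 for Pro2, and in the gid9 deletion they ranked higher among the variants of their library. Over the 20 variants with Thr2 the mean PSI was 4.59 ± 0.181 (SD, n = 2) in wild type and 5.03 ± 0.408 in the gid9 deletion, a difference of 0.437 (SE 0.526; limma, adjusted p = 0.408). The other 39 residue means were all lower in the gid9 deletion, as was the median over all 400 variants, which was lower by 0.789 in batch 1 and by 1.02 in batch 2 (by 0.118 and 0.276 with equal weight of bins). Relative to that median the Thr2 mean was higher by 1.34 (SE 0.190; limma, adjusted p = 0.0126; 0.0545 with the batch as a block), and the only other residue past the threshold was Gly2 (0.269; adjusted p = 0.0341; values relative to the median).

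No single variant passed the threshold in the gid9 deletion (0 of 400; limma with Benjamini-Hochberg adjustment). At an unadjusted p under 0.05 there were 48 variants, 1 higher and 47 lower. edgeR's quasi-likelihood test of reads in the upper against the lower bins called 3 variants, all higher (Thr2-Ile3, Thr2-Val3 and Thr2-Trp3, named after their values were seen). With the batch as a block 291 variants passed, 9 higher and 282 lower, and 8 of the 9 began with Thr2. With every bin weighted equally 21 passed, all higher, of which 16 began with Thr2. Leaving out the gid11 deletion library of batch 1 or that of batch 2 gave 10 in each case.

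Among the 17 lists of residue pairs fixed beforehand, 3 passed the test in the gid9 deletion, and all 3 hold Thr2. The Thr2 list ranked above the other variants (camera with a preset correlation, adjusted p = 2.91e-47; adjusted p = 0.158 with an estimated correlation), with a median difference of 0.544, made of 0.982 in batch 1 and 0.103 in batch 2. Its largest changes were those of Thr2-Trp3 (1.68), Thr2-Pro3 (−1.56) and Thr2-Val3 (1.15), none past the threshold over all variants, and 0 of 20 passed when adjusted over the list alone (17 of 20 relative to the library median). Thr2 followed by an aliphatic or aromatic residue 3 had a median difference of 0.976 (7 variants, adjusted p = 2.19e-24; adjusted p = 0.158 with an estimated correlation). When adjusted over the list alone, Thr2-Trp3 passed. Thr2 followed by a charged or polar residue 3 had a median difference of 0.434 (10 variants, adjusted p = 2.32e-22; adjusted p = 0.203 with an estimated correlation). Thr2 followed by Ala, Gly or Pro had a median difference of −0.388 and missed the threshold (adjusted p = 0.318), although Thr2-Pro3 passed when adjusted over the list alone.

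The remaining 13 lists had medians between −1.08 (Pro3) and −0.799 (acidic residue 3), near the shift of the library median, and missed the threshold (adjusted p between 0.155 and 0.857). They cover Ser2, Pro2, the other small residues 2, the NatB class, bulky hydrophobic and basic residues 2, and the aliphatic, aromatic, acidic, basic, polar, Pro and Gly or Ala residues 3. The Ser2 list, which shares with Thr2 a small hydroxyl side chain, went from a median PSI of 6.63 in wild type to 5.71 in the gid9 deletion, and the Pro2 list from 6.59 to 5.68. Centring on the library median called 0 Ser2 pairs in either deletion when adjusted over all 400 variants, and 1 and 2 when adjusted over the list alone. In settings added after seeing the data, which centre after removal of background, 3 Ser2 pairs named after their values were seen (Ser2-Ile3, Ser2-Lys3 and Ser2-Arg3) passed as higher in both deletions. With centring alone these were higher by 0.169, 0.187 and 0.677 in the gid9 deletion (lowest adjusted p = 0.0828; Ser2-Lys3 −0.0452 in batch 1 and 0.419 in batch 2) and by 0.472, 0.362 and 0.644 in the gid11 deletion (lowest adjusted p = 0.0517). With the stop profile subtracted as well they were higher by 0.557, 0.475 and 0.543 in the gid9 deletion and by 0.522, 0.396 and 0.530 in the gid11 deletion (largest adjusted p = 0.0117 and 0.0133), and with bins 1 to 3 left out by 0.442 to 0.537 and by 0.433 to 0.527 (adjusted p = 0.00275 and 0.00302). Of the residue means at position 2, Asn2, Tyr2, Lys2, Ile2 and His2 differed most (−1.07 to −0.941). At position 3 these were Thr3, Pro3, Ala3, Ser3 and Met3 (−1.05 to −0.867). None passed (lowest adjusted p = 0.176), while 39 of the 40 residue means were lower past the threshold with the batch as a block.

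The gid11 deletion removes the substrate receptor instead of the catalytic module, and here too Thr2 stood apart in MXZ-Phm8. The Thr2 mean was 5.54 ± 0.721 (SD, n = 2) against 4.59 ± 0.181 in wild type, a difference of 0.950 (SE 0.526; limma, adjusted p = 0.358; 0.0129 with the batch as a block). The other 39 residue means were lower, and the median of all variants was lower by 0.312 in batch 1 and by 0.984 in batch 2 (by 0.0711 and 0.403 with equal weight of bins). Relative to that median the Thr2 mean was higher by 1.60 (SE 0.190; limma, adjusted p = 0.00451; 0.0590 with the batch as a block), and no other residue mean passed.

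No single variant passed the threshold in the gid11 deletion (0 of 400, limma), with 23 at an unadjusted p under 0.05, 10 higher and 13 lower. The edgeR test called 3, all higher, the same pairs as in the gid9 deletion (Thr2-Ile3, Thr2-Val3 and Thr2-Trp3). With the batch as a block 25 variants passed: the 11 that were higher all began with Thr2, and 14 were lower. With every bin weighted equally 19 passed, 17 higher and 2 lower, and 15 of the 17 began with Thr2. Centring on the library median gave 4, namely Thr2 followed by Ile, Lys, Val or Trp. Without the gid11 deletion library of batch 1 there were 12, and without that of batch 2 there were 6.

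In the gid11 deletion 5 of the 17 lists passed. The Thr2 list ranked above the other variants (camera, adjusted p = 7.55e-70; adjusted p = 0.0751 with an estimated correlation), with a median difference of 1.16, made of 1.74 in batch 1 and 0.467 in batch 2. Its largest changes were those of Thr2-Trp3 (2.17), Thr2-Val3 (1.94) and Thr2-Ile3 (1.74). When adjusted over the list alone 5 of 20 passed, these 3 with Thr2-Leu3 and Thr2-Cys3 (18 of 20 relative to the library median). Thr2 followed by an aliphatic or aromatic residue had a median difference of 1.59 (adjusted p = 2.96e-33; adjusted p = 0.0751 with an estimated correlation; 6 of 7 adjusted over the list alone). The median was 0.896 for a charged or polar residue 3 (adjusted p = 5.52e-25; adjusted p = 0.171 with an estimated correlation; 0 of 10 adjusted over the list alone, 10 of 10 relative to the library median) and 0.246 for Ala, Gly or Pro (adjusted p = 0.00711; adjusted p = 0.645 with an estimated correlation).

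Pairs with a bulky hydrophobic residue 2 ranked below the others in the gid11 deletion (120 variants, median −0.626, adjusted p = 0.0419; adjusted p = 0.996 with an estimated correlation). Relative to the library median that list's median was 0.0212 and its mean −0.0344, so that they differ in sign. The remaining 12 lists had medians between −0.683 (Gly3 or Ala3) and −0.575 (acidic residue 3) and missed the threshold (adjusted p between 0.377 and 0.982). The Ser2 list went from a median PSI of 6.63 to 6.00 and the Pro2 list from 6.59 to 5.95. After Thr2, the residue means that differed most at position 2 were Met2, His2, Trp2 and Leu2 (−0.820 to −0.693). At position 3 they were Pro3, Gln3, Ala3, Met3 and Thr3 (−0.712 to −0.626). None passed, whereas with the batch as a block 34 did, Thr2 higher and 33 lower. Without the gid11 deletion library of batch 1 there were 39.

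**Figure D2:**
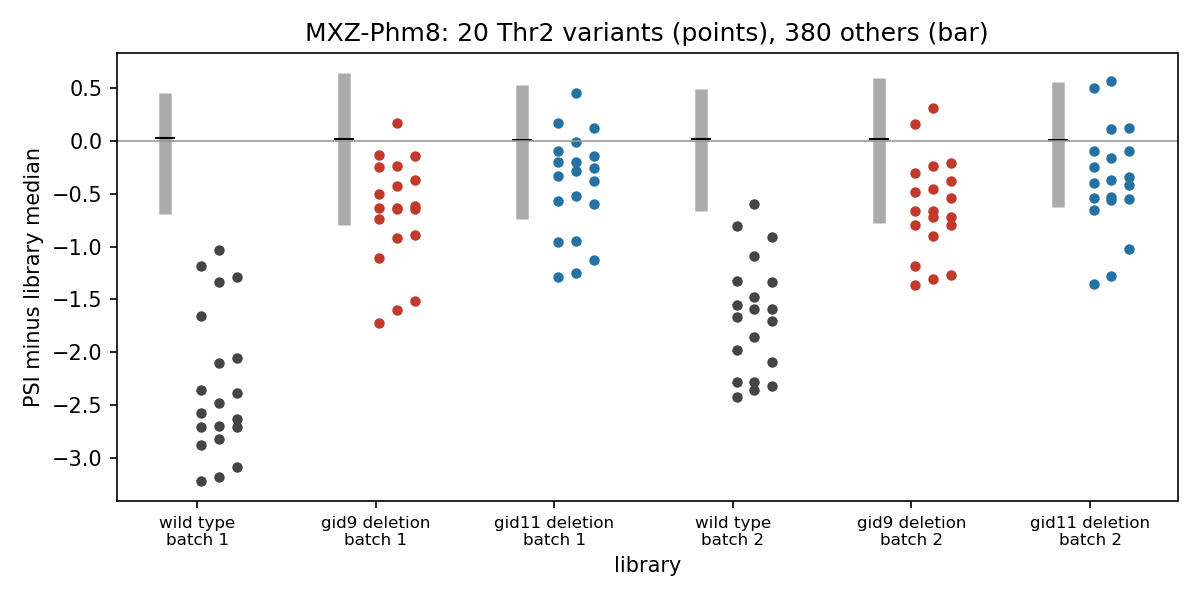
PSI of MXZ-Phm8 variants relative to the median of their library, in each of the 6 libraries; points are the 20 variants with Thr2, and the bar spans the 5th to 95th percentile of the 380 others with a tick at their median. The 20 Thr2 variants lie below the bar's tick in wild type, and in the mean of the batches all but Thr2-Pro3 lie nearer to it in both deletions.

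The deletions were also set against each other, to ask whether losing the receptor and losing the catalytic module act alike on Phm8. The native pair was 0.593 higher in the gid11 deletion (limma, adjusted p = 0.969), and the Thr2 mean was 0.513 higher (SE 0.526, adjusted p = 0.807). These differences turned to −0.122 and −0.108 when every bin was weighted equally. No variant passed (0 of 400, limma), 4 had an unadjusted p under 0.05 (3 higher, 1 lower), and edgeR called 0. With the batch as a block 3 passed, Lys2-Met3 and Met2-Val3 higher and Met2-Gln3 lower in the gid11 deletion (named after their values were seen). Equal weight of bins gave 4, all lower, namely Met2 followed by Asp, Lys, Asn or Gln, and the median bin gave 3, Lys2-Met3 and Thr2-Pro3 higher and Met2-Gln3 lower. Leaving out the gid11 deletion library of batch 2 gave 1.

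By list, 3 of 17 passed between the deletions. The Thr2 list had a median difference of 0.554 (camera, adjusted p = 0.00313; adjusted p = 0.989 with an estimated correlation), Thr2 with an aliphatic or aromatic residue 0.612 (adjusted p = 0.0243; adjusted p = 0.989 with an estimated correlation) and Thr2 with Ala, Gly or Pro 0.634 (adjusted p = 0.0433; adjusted p = 0.989 with an estimated correlation). The largest differences in the Thr2 list were those of Thr2-Tyr3 (0.946), Thr2-Pro3 (0.897) and Thr2-Val3 (0.787), and 0 of 20 passed when adjusted over the list alone. The Thr2 list ranked lower, not higher, with equal weight of bins (adjusted p = 0.813). The other 14 lists missed the threshold (adjusted p between 0.564 and 0.938; medians 0.198 to 0.416). None of the 40 residue means passed. After Thr2 the largest at position 2 were Asn2, Ile2, Lys2 and Tyr2 (0.384 to 0.342), and at position 3 Thr3, Ser3, Val3, Ala3 and Pro3 (0.423 to 0.324).

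In MXZ-Gpm3 the same pairs of residues were placed on the other protein, and the largest differences again belonged to Thr2. The native pair Thr2-Val3 went from a PSI of 4.42 in wild type to 7.95 in the gid9 deletion, a difference of 3.54, and Thr2-Ile3 from 4.79 by 3.16. Thr2-Trp3 (2.91), Thr2-Leu3 (2.78), Thr2-Cys3 (2.39), Thr2-Tyr3 (2.09), Thr2-Gln3 (1.94), Thr2-Phe3 (1.74), Thr2-Lys3 (1.18) and Thr2-His3 (1.06) completed the 10 variants that were higher by over 1. In the gid11 deletion the same 10 pairs led, from 3.20 for Thr2-Val3 and 2.85 for Thr2-Ile3 to 0.826 for Thr2-Lys3 and 0.724 for Thr2-His3, and 8 were higher by over 1. With 1 library per genotype these differences have no replicate check, and the counting errors of the 10 (0.00177 to 0.00518) cover reads only. Of the 380 pairs without Thr2, 0 were higher by over 1 in either deletion, and the highest, Val2-Trp3 (named after its value was seen), was higher by 0.914 and 0.465.

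Most other Gpm3 variants were already near the top of the scale, with a median PSI over all 400 of 7.68 in wild type, 7.94 in the gid9 deletion and 7.57 in the gid11 deletion. In the inferred bin order all 400 were higher in the gid9 deletion than in wild type and 20 of 400 in the gid11 deletion, with medians of 0.257 and −0.117. With the 2 highest bins exchanged, the next best order, 8 and 382 of 400 were higher, with medians of −0.168 and 0.0602, so these directions rest on the order of the top bins. The Thr2 list had a median PSI of 6.95 in wild type and a median difference of 0.995 in the gid9 deletion and 0.662 in the gid11 deletion, both at percentile 100 of 10000 random lists matched on reads. With these bins exchanged the medians were −0.164 and 0.0642, near those of all variants, while 6 and 7 variants, all with Thr2, were still higher by over 1 and the native pair was higher by 2.62 and 2.85. Thr2 with an aliphatic or aromatic residue 3 had medians of 2.78 and 2.44, Thr2 with a charged or polar residue 0.640 and 0.312, and Thr2 with Ala, Gly or Pro 0.311 and −0.0321.

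The Ser2 list on Gpm3 had medians of 0.251 and −0.109, Pro2 0.274 and −0.146, and the other small residues 2 0.264 and −0.120. The NatB class had 0.249 and −0.126, bulky hydrophobic residues 2 0.248 and −0.111, and basic residues 2 0.254 and −0.126. At position 3 the 7 lists had medians of 0.251 to 0.275 in the gid9 deletion and −0.122 to −0.108 in the gid11 deletion. In the inferred bin order no variant was lower in the gid9 deletion, and the lowest differences in the gid11 deletion were small (Lys2-Trp3 −0.256, Met2-Trp3 −0.220, Cys2-Gln3 −0.220, and 7 more down to Gly2-Phe3 at −0.182). Between the deletions 0 of 400 variants were higher in the gid11 deletion, with a median of −0.372 and the largest difference at Lys2-Trp3 (−0.686), but with the 2 highest bins exchanged all 400 were, with a median of 0.229. The Thr2 list differed by −0.335, against −0.366 for Ser2 and −0.425 for Pro2.

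**Figure D3:**
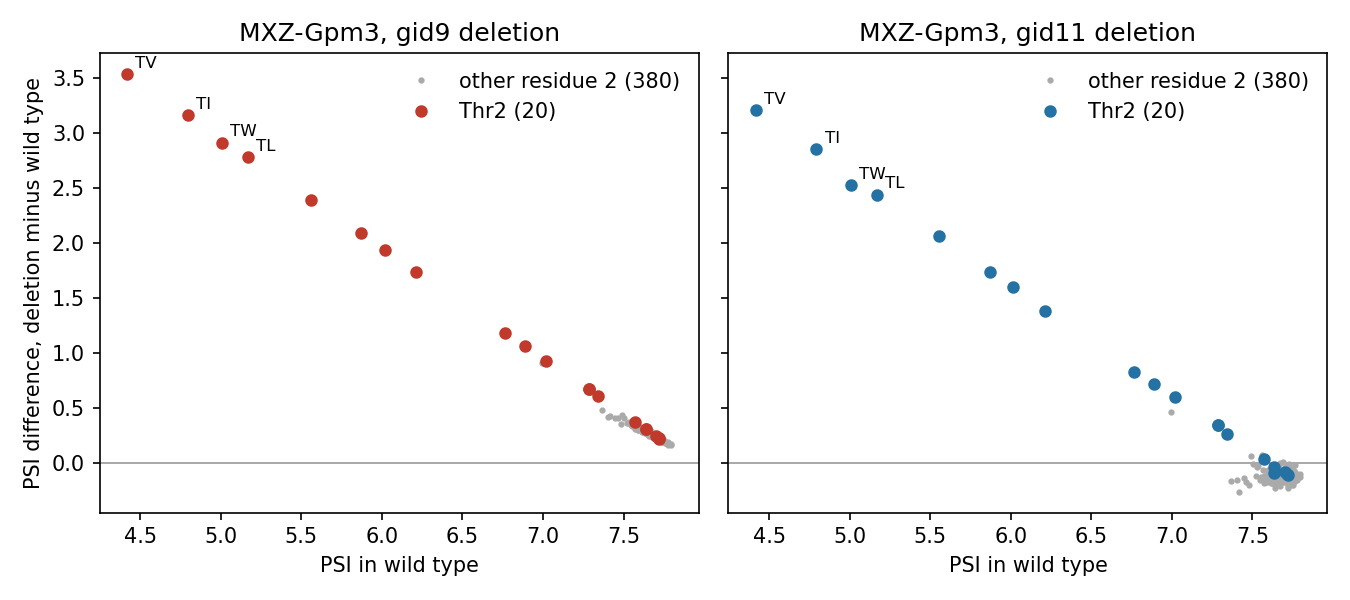
Difference in PSI from wild type for the 400 residue pairs of MXZ-Gpm3 in the gid9 deletion and the gid11 deletion, plotted against the PSI in wild type, with Thr2 pairs marked. The 10 pairs higher by over 1 in the gid9 deletion all carry Thr2, up to 3.54 for Thr2-Val3.

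MX9-Phm8 extends the question to residues 2 to 10. In wild type 84.5% of the reads came from peptides with 6 to 9 changed residues, 4.98% from the native peptide and 9.89% from single substitutions, so each residue was averaged over all 5610 peptides that reached the read minimum. Thr2 again had the largest mean difference at position 2: over 1216 peptides with Thr2 the mean PSI was 5.03 in wild type and higher by 0.498 in the gid9 deletion and by 0.498 in the gid11 deletion, while the median over all peptides was lower by 0.199 and 0.148. Among the Thr2 peptides, a split made after seeing the data, the single substitutions had a mean difference of 1.72 and 1.63, whereas the 996 with 6 to 9 changed residues had a median of 0.162 and 0.189, with 102 and 101 of them higher by over 1. Pro2 came next in the gid9 deletion (0.290) and was lower in the gid11 deletion (−0.214). At most other positions the native residue had the highest mean difference, with Lys5 at 1.12 and 1.06, Asp6 at 0.948 and 0.878, Tyr7 at 0.738 and 0.631, Ile3 at 0.444 and 0.365, Ala4 at 0.415 and 0.391, Arg8 at 0.354 and 0.255 and Thr9 at 0.433 and 0.404. At position 10 Met was highest (0.569 and 0.638, from 6 peptides) and the native Ile next (0.328 and 0.269). These means of native residues include the native peptide and the single substitutions that keep the residue, most of which were higher by over 1. The make-up of the library thus favours the native residue at each position, so its rank does not show that the residue matters. Single substitutions of Lys5, for example, were themselves higher by a mean of 2.18 and 2.09. Only Thr2 was split by the number of changes. Averaged over positions 4 to 10, residue means differed by −0.0301 and −0.0715 for Pro, by 0.0289 and 0.0358 for Asp or Glu, by −0.0248 and −0.0342 for His, Lys or Arg and by 0.00284 and −0.0496 for hydrophobic residues.

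The 171 single substitutions of the Phm8 N-terminus show which native residues matter when the rest is kept. Substitutions of Thr2 had the highest wild type PSI: the 19 of them had a mean of 6.21 ± 0.519 (SD over substitutions), against 4.69 for the native peptide, with a mean difference of 0.161 in the gid9 deletion and 0.0372 in the gid11 deletion. They were not uniform: T2S (5.83 in wild type) was higher by 0.690 and 0.593, and T2G (4.86) was higher by 0.815 in the gid9 deletion and lower by 0.231 in the gid11 deletion (both named after their values were seen). Asp6 came next with a mean of 6.05 in wild type and differences of 0.743 and 0.579. Substitutions of Ile3, Ala4 and Tyr7 had wild type means of 5.35, 5.14 and 5.36. Those of Lys5 (4.56), Arg8 (4.69), Thr9 (4.94) and Ile10 (4.97) stayed near the native value. In the deletions every position had a mean between 6.25 and 6.99, and 135 of 171 substitutions were higher by over 1 in the gid9 deletion and 130 in the gid11 deletion. Position 2 lay at percentile 0 of matched random lists in both comparisons and position 6 at percentile 0.01, and the medians for Pro, Asp or Glu, basic and hydrophobic substitutions at positions 4 to 10 lay between 1.56 and 1.90.

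The largest positive differences among single Phm8 substitutions were at Lys5, Arg8 and Ala4, where wild type PSI was low. K5Y was higher by 2.97 in the gid9 deletion and by 2.88 in the gid11 deletion (3.80 in wild type). R8W (2.69 and 2.70), R8H (2.68 and 2.53), K5F (2.65 and 2.64), A4E (2.61 and 2.56), K5C (2.60 and 2.52), K5W (2.59 and 2.61) and R8Y (2.55 and 2.46) led in both. K5I (2.66) and R8C (2.63) were among the 10 largest in the gid9 deletion, and K5H (2.46) and R8F (2.45) in the gid11 deletion. Only T2W (−0.0740), T2V (−0.0650) and T2R (−0.0523) were lower in the gid9 deletion, and these with T2G (−0.231) and T2E (−0.0255) in the gid11 deletion. Between the deletions the median difference was −0.0820 (0.0664 with the 2 highest bins exchanged), the lowest difference was that of T2G (−1.05) and the highest that of Y7M (0.222).

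Over all peptides of MX9-Phm8 with 500 or more reads, the highest differences in the gid9 deletion were mostly of peptides that began with Pro or Gly. PSLSWAESW was higher by 4.38 (2.77 in wild type), followed by NINSFSSCI (3.80), PSLSSSLQC (3.69), PSLYSLAGL (3.47), GYSFGRREV (3.43) and GLPCTYHVI (3.39). The other 4 of the 10, PSLGRPRWL, PSLADHQPR, PTFISVSVV and PSLNNISGR, were higher by 3.30 to 3.37. In the gid11 deletion 9 of the 10 highest differences were single substitutions of the native peptide, and the other was TLGPYDPYL (2.73). TLVVVWWRP was lowest in both deletions (−2.83 and −2.81). CRLVACLVF (−2.25) and LWRLWPLQL (−2.001) followed in the gid9 deletion, and LWRLWPLQL (−1.88) and CRLVACLVF (−1.80) in the gid11 deletion. Between the deletions the largest differences were all lower in the gid11 deletion, led by GIDGRYRTI (−4.43), PSLSWAESW (−4.38) and NINSFSSCI (−4.03), while the highest was CLVVYFVLV (1.42).

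In MX9-Gpm3 nearly all reads belonged to the native peptide (41.2% in wild type) or to single substitutions (56.7%). Thr2 was again the residue whose substitutions had the highest wild type PSI: all 19 together had a mean of 7.47 ± 0.0680 (SD over substitutions) against 4.20 for the native peptide, and all 19 were over 1 above it. Val3 followed with 6.48 ± 0.987. The means of positions 4 to 8 were 4.63, 4.22, 4.58, 4.75 and 4.36, and those of Leu9 and Phe10 were lower than the native peptide, at 3.15 ± 1.16 and 2.59 ± 0.957. In the gid9 deletion positions 2 to 8 had means of 7.25 to 7.50 and in the gid11 deletion of 7.71 to 7.89, while position 9 reached 5.21 and 5.50 and position 10 reached 4.31 and 4.52.

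The differences from wild type for Gpm3 were therefore smallest at position 2 (−0.00927 in the gid9 deletion and 0.379 in the gid11 deletion, percentile 0 in both; 0.228 and 0.0156 with the 2 highest bins exchanged) and largest at position 5 (3.27 and 3.64). They were 1.02 and 1.42 at position 3, 2.86 and 3.25 at position 4, 2.68 and 3.14 at position 6, 2.50 and 2.96 at position 7, 2.97 and 3.41 at position 8, 2.06 and 2.35 at position 9 and 1.72 and 1.93 at position 10. Of 171 substitutions 123 were higher by over 1 in the gid9 deletion and 130 in the gid11 deletion. T4A was highest in both (4.20 and 4.57, from 3.31 in wild type), and T4C (4.16 and 4.53), T4Q (4.01 and 4.43), T6K (3.87 and 4.28), T4G (3.87 and 4.27), T4S (3.85 and 4.21), F10V (3.83 and 4.16), D5E (3.83 and 4.24) and F10L (3.74 and 4.22) followed, with F10I (3.72) in the gid9 deletion and D5W (4.25) in the gid11 deletion. T2W (−0.144), T2E (−0.138) and T2G (−0.137) were lowest in the gid9 deletion. Substitutions that keep Thr2 had a median difference of 2.74 and 3.20. Centring on the library median turned these to −0.161 and −0.128, because nearly all variants of this library keep Thr2 and set that median. The Gpm3 medians for Pro (2.47 and 2.93), Asp or Glu (2.68 and 3.23), basic (2.61 and 3.07) and hydrophobic (2.75 and 3.13) substitutions at positions 4 to 10 lay within the random lists. Between the deletions the median was 0.397 higher in the gid11 deletion (−0.236 with the 2 highest bins exchanged), with T6M highest (0.920) and L9D lowest (−0.132).

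**Figure D4:**
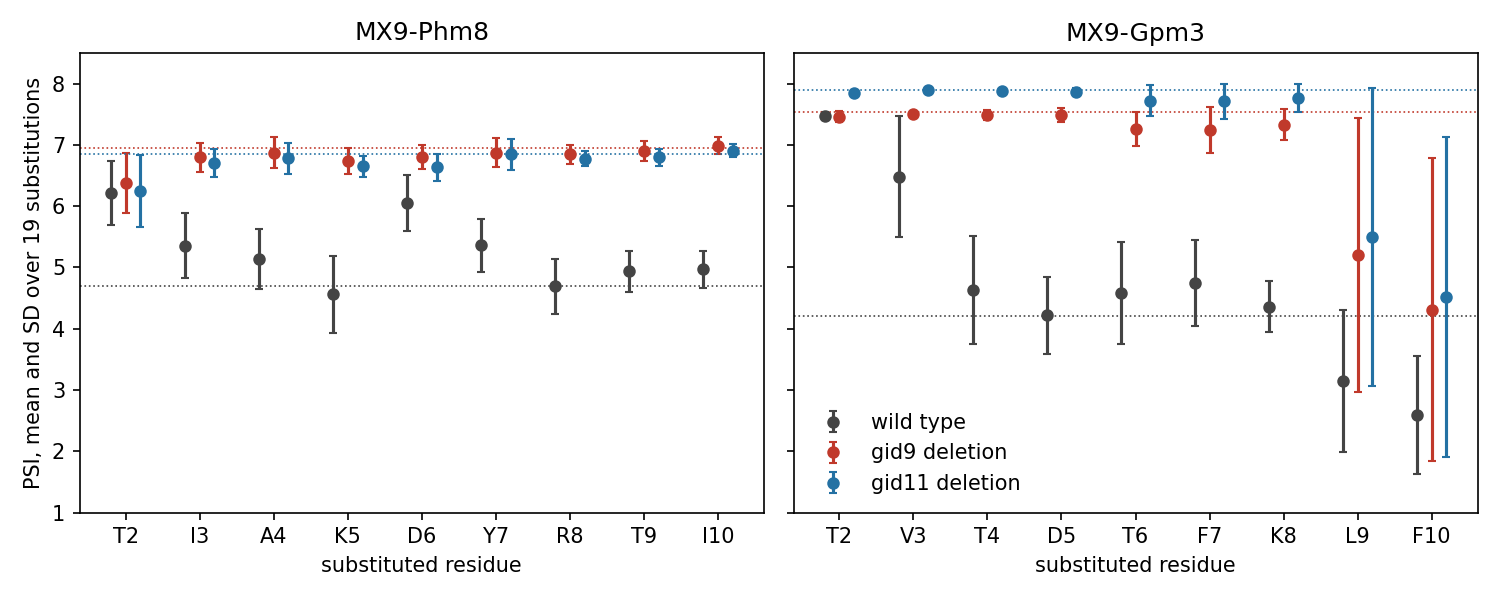
Mean PSI of the 19 single substitutions at each of the positions 2 to 10 of Phm8 and Gpm3 in MX9 libraries, by genotype; bars are the SD over substitutions and dotted lines the native peptide. Position 2 has the highest mean in wild type in both proteins (6.21 and 7.47) and changes least in the deletions.

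Libraries that share variants were compared across variants, which are not independent replicates. In wild type the MXZ-Phm8 batches correlated with r = 0.851 (Spearman rho 0.783, 400 variants), MXZ-Phm8 and MX9-Phm8 with r = 0.882 and 0.890 for batches 1 and 2 (39 shared variants), MXZ-Gpm3 and MX9-Gpm3 with r = 0.998 and MXZ-Phm8 and MXZ-Gpm3 with r = 0.677 and 0.515. For MXZ-Phm8 and MXZ-Gpm3 the ranks correlated less (Spearman rho 0.266 and 0.245), and r was 0.297 and 0.250 with equal weight of bins. For MXZ-Gpm3 and MX9-Gpm3 the Spearman rho was 0.940, and with equal weight of bins r was 0.874 and rho 0.638. The same libraries gave r = 0.544 in the gid9 deletion and 0.663 in the gid11 deletion (0.253 and 0.137 with equal weight of bins). In the gid9 deletion the MXZ-Phm8 batches gave r = 0.494, and in the gid11 deletion 0.627. MXZ-Phm8 and MX9-Phm8 gave r = −0.233 and −0.221 in the gid9 deletion, which turned to 0.638 and 0.695 with equal weight of bins, and 0.349 and 0.170 in the gid11 deletion. MXZ-Phm8 and MXZ-Gpm3 gave r of −0.0242 and −0.0744 in the gid9 deletion.

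Variants with a stop codon at a varied position cannot make the fusion and served as background. They held 51.5%, 66.9% and 60.5% of the reads in wild type, gid9 deletion and gid11 deletion in batch 1 of MXZ-Phm8, and 63.5%, 77.1% and 72.6% in batch 2 (exact 95% intervals within 0.1 of these values). Their PSI lay between 2.30 and 2.92, against 5.31 to 6.60 for all other reads. In the other 9 libraries they held between 0.175% and 1.24%, and there their PSI lay between 4.17 (MX9-Gpm3, wild type) and 7.22 (MXZ-Gpm3, gid9 deletion). Stop variants were left out of every comparison above, but between 8.34% and 20.9% of the remaining MXZ-Phm8 reads lay in the bins 1 to 3 that stop variants fill.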

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

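All tests of explanation here were chosen after seeing the result, except those of uneven bases and of Gly2-Ile3, whose predictions were written before their values.

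Reads with a stop codon were singled out because they lie outside the comparisons and exceed what random codons give. In MXZ-Phm8 they made up 51.5% (wild type), 66.9% (gid9 deletion) and 60.5% (gid11 deletion) of the reads in batch 1 and 63.5%, 77.1% and 72.6% in batch 2, against 9.16% of all codon pairs. A few sequences that take most of the counts were excluded as the cause, since the median stop sequence had at least 15.2 times the reads of the median other sequence in all 6 libraries. Uneven bases in the random codons were excluded too, since the bases of the other reads give at most 8.33%. Whether cells with a stop variant grew better or were sorted more often was not tested, and no biological explanation was tested.

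The median PSI of MXZ-Phm8 was singled out because it was lower in the gid9 deletion than in wild type in both batches (−0.789 and −1.02) while that of MXZ-Gpm3 was higher (0.257). The difference between the library types was not tested, and with bins 7 and 8 exchanged MXZ-Gpm3 was lower too (−0.168, against −0.592 and −1.05), so the contrast in direction rests on the bin order. With equal weight of bins the shifts in MXZ-Phm8 were −0.118 and −0.276 in the gid9 deletion and −0.0711 and −0.403 in the gid11 deletion. Reads that follow the stop profile were excluded as the whole cause, since after their subtraction the shifts in batches 1 and 2 were still −0.600 and −0.690 in the gid9 deletion, while in the gid11 deletion they were −0.119 and −0.864 (before it −0.312 and −0.984). A lower stability of every Phm8 fusion in the deletions remains open: the 19 substitutions of Thr2 in MX9-Phm8 were higher by 0.161 in the gid9 deletion and by 0.0372 in the gid11 deletion, and the peptides with 6 to 9 changed residues and a residue 2 other than Thr were lower by a median of 0.269 and 0.193, but the gates of the sorts are not stated and so may differ between libraries.

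In MX9-Phm8 wild type 84.5% of the reads came from peptides with 6 to 9 changed residues, which was singled out because the planned single substitutions leave these reads out.

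Peptides of MX9-Phm8 with Pro2 or Gly2 that were higher in the gid9 than in the gid11 deletion were weighed as well. Few reads per peptide were not excluded as the cause. The 475 Pro2 peptides with 500 or more reads in each library had a median difference of 0.0345 against −0.0713 for random lists (percentile 100), so the Pro2 median stayed above them at that depth. But these are most of the 521 Pro2 peptides, which were picked for the pattern. A median also does not address the peptides higher by over 1, and Gly2 peptides were not tested. Clones with a second change elsewhere allow no dependence on residue 4, but among Pro2 peptides the share higher by over 1 did depend on it. It was 73.2% with Leu4 (lower 95% limit 62.2%) and 90.9% with Phe4, against 13.4% with a residue 4 other than Leu. Such clones were still not excluded, since the bound written for Leu4, over 3 times any other residue, was not reached. Gly2 peptides were not split by residue 4. A difference found in 1 sort only was excluded for Gly2-Ile3 alone, which in MXZ-Phm8 relative to the library medians was 1.71 and 0.887 higher in batches 1 and 2, while Pro2-Ile3 (−0.514 and 0.0553), Pro2-Ser3 (0.0427 and −0.0449) and Gly2-Ser3 (−0.0266 and 0.0396) showed no such difference in both batches. A receptor of the ligase other than Gid11 for Pro2 remains open, because its test ran on the peptides picked for the pattern: against wild type their median was −0.102 in the gid9 deletion (random lists −0.239, percentile 100) and −0.214 in the gid11 deletion (random lists −0.169, percentile 0), and peptides with Pro3 lay at percentile 1.36 in the gid9 deletion.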

How the results depend on the processing

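Of the results that answer a comparison, 263 values under alternatives stayed on their side of the threshold, 80 passed it anew, 47 moved, 14 no longer passed and 6 reversed; of the others 153 stayed, 20 passed anew, 13 no longer passed, 7 moved and 11 reversed. Where a result changed, the cause was not tested, unless stated. The counts of variants are the results least settled: over 12 planned settings, 6 gave calls for the gid9 deletion, 5 for the gid11 deletion and 3 between the deletions, and over 6 settings added after seeing the data 5, 6 and 0. Where a library was left out, its genotype's lone sample was assumed to vary like the other groups. Minima of 1, 30 and 500 reads do not test depth for MXZ variants, whose median reads per library were 9353 or more.

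With the batch as a block (the paired fit), 291, 25 and 3 variants passed for gid9 deletion, gid11 deletion and between the deletions, 39 and 34 residue means for the deletions, and the native pair passed at 1.15 and 1.74; without centring the block changed no other call listed for these comparisons, apart from that of the Thr2 mean in the gid11 deletion. Centring with the block gave 1 and 4 variants, as centring alone did, but 1 and 0 residue means instead of 2 and 1, and the Thr2 mean no longer passed in either deletion (adjusted p = 0.0545 and 0.0590).

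The direction of the called variants varied with the setting. With the median bin 9 of 10 were lower in the gid9 deletion and 8 of 13 in the gid11 deletion. With the stop profile subtracted or bins 1 to 3 left out, before centring, all 13 in each deletion were higher and began with Thr2. Variants past the threshold, gid9 deletion and gid11 deletion: equal weight of bins 21 and 19 (4 between the deletions), centring 1 and 4, median bin 10 and 13 (3 between), stop profile subtracted 13 and 13, with centring 21 and 19, bins 1 to 3 left out 13 and 13, with centring 23 and 22, bins 7 and 8 exchanged 1 for the gid11 deletion, only the 2 groups compared 10 for the gid9 deletion, edgeR 3 and 3. With libraries left out in turn they ran from 0 to 10, 0 to 12 and 0 to 1 (between).

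The native pair in the gid9 and gid11 deletion: equal weight of bins 2.29 and 2.17, stop profile subtracted 2.68 and 2.76, with centring 3.33 and 3.25, bins 1 to 3 left out 2.29 and 2.39, with centring 2.92 and 2.88, edgeR (log2) 2.72 and 3.28, and for the gid11 deletion centring 2.39 and median bin 2.81. Left out in turn: 0.707 to 2.45 and 1.29 to 2.79. Between the deletions it reversed with equal weight of bins (−0.122), with the stop profile subtracted and centring (−0.0768) and with bins 1 to 3 left out and centring (−0.0431). The Thr2 mean reversed there in the same 3 settings (−0.108, −0.0238, −0.0309), and the Thr2 list in 4 (adjusted p = 0.813 with equal weight, 0.968 with the stop profile subtracted, 0.798 with bins 1 to 3 left out and 0.746 with centring after that; over all alternatives 4.83e-06 to 0.989).

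Residue means past the threshold, gid9 and gid11 deletion: equal weight of bins 1 and 1, centring 2 and 1, stop profile subtracted 1 and 1, with centring 9 and 3, bins 1 to 3 left out 1 (gid11 deletion), with centring 16 and 12, only the 2 groups compared 32 (gid9 deletion), left out in turn 0 to 32 and 0 to 39. Lists past the threshold: in the gid9 deletion 5 with synonymous sequences averaged, 7 and 7 with centring after the stop profile or bins 1 to 3 were removed; in each comparison 0 with the estimated correlation and 0 with centring as well; left out in turn 3 to 4 (gid9 deletion), 3 to 5 (gid11 deletion) and 0 to 3 (between). Between the deletions 0 with equal weight, 1 with centring, 1 with synonymous sequences averaged, 0 with the stop profile subtracted, 1 with centring after that, 1 with bins 1 to 3 left out and 0 with bins 7 and 8 exchanged.

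The Thr2 median of MXZ-Gpm3 (gid9 and gid11 deletion): equal weight of bins 0.424 and 0.213, centring 0.738 and 0.776, floor per bin 1.02 and 0.704, median bin 1.00 and 0.771, bins 7 and 8 exchanged −0.164 and 0.0642. The Thr2 mean of MX9-Phm8: single substitutions 1.72 and 1.63, 30 reads 0.608 and 0.605, 500 reads 0.561 and 0.553, equal weight 0.357 and 0.416, centring 0.747 and 0.707, floor 0.556 and 0.553, median bin 0.597 and 0.601, synonymous sequences 0.503 and 0.501, bins 7 and 8 exchanged 0.549 and 0.584. Substitutions that keep Thr2 in MX9-Gpm3: equal weight 1.80 and 1.80, centring −0.161 and −0.128 (by construction, since these variants set the median), floor 2.78 and 3.24, median bin 2.76 and 3.32, synonymous sequences 2.78 and 3.16, bins 7 and 8 exchanged 2.54 (gid11 deletion). With equal weight of bins the gid9 deletion batches correlated with 0.710, and correlations in the gid9 deletion turned to 0.123 and 0.191 (MXZ-Phm8 and MXZ-Gpm3) and to 0.638 and 0.695 (MXZ-Phm8 and MX9-Phm8).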

Other observations

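The test of the hypothesis below was chosen after seeing the result. The prediction for Gly2-Ile3 was written before its values, but it does not test this hypothesis, which concerns Pro2. Among MX9-Phm8 peptides with 6 to 9 changed residues, 119 of 521 with Pro2 (22.8%) and 49 of 561 with Gly2 (8.73%) were higher by over 1 in the gid9 than in the gid11 deletion, against 6 of 996 with Thr2 and 24 of 3249 with any other residue 2. Against wild type, 102 Pro2 peptides were higher by over 1 in the gid9 deletion and 2 in the gid11 deletion. With Pro2-Ser3-Leu4 there were 26 of 29, with median PSI of 3.56 in wild type, 6.15 in the gid9 deletion and 3.23 in the gid11 deletion. By residue 4, the count was 60 of 82 for Leu, 10 of 11 for Phe, 8 of 14 for Ile, 17 of 40 for Pro, 12 of 38 for Val, 1 of 75 for Arg and 0 of 110 for Gly. In MXZ-Phm8 the pair Gly2-Ile3 had a PSI of 4.90, 5.65 and 4.42 in wild type, gid9 deletion and gid11 deletion in batch 1, and 4.85, 5.17 and 4.32 in batch 2. The other pairs there that join Pro2 or Gly2 with Ile3 or Ser3 showed no such difference in both batches. Relative to the library medians, the gid9 minus the gid11 deletion was −0.514 and 0.0553 for Pro2-Ile3, 0.0427 and −0.0449 for Pro2-Ser3, and −0.0266 and 0.0396 for Gly2-Ser3.

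The hypothesis is that another receptor of the ligase, such as Gid4 or Gid10, which are known to bind N-terminal Pro, acts on some Pro2 peptides and needs the catalytic module but not Gid11. Its test (percentile 100 for the gid9 deletion and 0 for the gid11 deletion against wild type) ran on peptides picked because they showed the pattern, so it decides nothing, and no receptor other than Gid11 was deleted. Gly2 peptides were left out of it, since they had a median of −0.270 in the gid9 deletion (percentile 1.44) and −0.227 in the gid11 deletion (percentile 0) against wild type, and of −0.0639 (percentile 86.4) for the gid9 minus the gid11 deletion.

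Residues 9 and 10 of Gpm3 were chosen after their values were seen. Substitutions with a PSI under 3 in all 3 genotypes numbered 0 of 19 at each of the positions 2 to 8, 5 of 19 at Leu9 (L9D, L9E, L9K, L9P, L9R) and 9 of 19 at Phe10 (F10D, F10E, F10G, F10K, F10N, F10P, F10Q, F10R, F10S), and 0 of 171 in MX9-Phm8. L9D had 1.70, 1.89 and 1.76 in wild type, gid9 deletion and gid11 deletion, and F10D had 1.62, 1.66 and 1.75. L9I had 4.17, 7.61 and 7.91, and F10Y had 4.47, 7.55 and 7.92.

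Substitution to Met was also chosen after its values were seen. In MX9-Phm8 it had the highest wild type PSI of the 19 at all 7 positions from 4 to 10, with A4M at 6.43, K5M at 6.14 and D6M at 6.91, and exceeded the mean of the other 18 by 1.16 in wild type, 0.417 in the gid9 deletion and 0.302 in the gid11 deletion. In MX9-Gpm3 it was highest at 2 of 7 positions (D5M 6.56, F7M 6.55), with a mean excess of 1.097, 0.493 and 0.489. By position the excess ran from −0.0785 to 2.48 in wild type, from −0.286 to 2.39 in the gid9 deletion and from −0.137 to 2.51 in the gid11 deletion. In both deletions the highest was that of F10M.

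Without use of the bin order, the share of a variant's reads that lie in other bins than in wild type had a median of 74.2% for Thr2 pairs of MXZ-Gpm3 and 22.8% for other pairs in the gid9 deletion, and 44.9% and 9.94% in the gid11 deletion. For single substitutions that keep Thr2 against those of Thr2 it was 76.8% and 8.71% (gid9 deletion) and 76.6% and 2.33% (gid11 deletion) in MX9-Phm8, and 91.8% and 16.2%, and 96.5% and 23.8%, in MX9-Gpm3.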
